A study of Oryctolagus cuniculus with 6 samples.

How the data were processed

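ATAC-seq libraries were made from 6 corneas of female rabbits, 3 naive and 3 with an alkali burn, collected on day 14. Per the labels' protocols, a filter disc of 8 mm soaked in sodium hydroxide lay on the cornea for 30 s, and 1 eye of each rabbit was burned. The labels give the concentration as 0.5 N in the treatment protocol and as 1 N among the sample characteristics, and this conflict could not be settled. Nuclei were isolated from 30 to 50 mg of frozen tissue, and about 100000 were treated with the enzyme of a commercial ATAC kit. The libraries come from separate corneas, but the labels do not tie the library numbers to animals, so the numbers were not used as pairs in the main tests.

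Per the submitters' processing notes, FastQC, Bowtie2 and SAMtools were used with the build OryCun2.0, with no versions given. The peak caller, the handling of duplicate reads and mitochondrial reads, and any shift of reads for the transposase's cut were not given in the sources used here. The authors called peaks separately for each library. Each deposited list has 10 columns without a header. The deposited fold value is the ratio of tags at the summit to the local background, and the authors also gave the -log10 of the p-value and of the q-value of each peak. The deposited score is an integer made from the -log10 q-value, which held for 99.98% to 100% of the peaks of a list. These values were used to describe, rank or filter peaks within a list.

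The total read number is not in the lists, so depth was recovered from them. For each peak, the fold and the p-value were solved together for the whole number of tags at the summit and the local background, with the fold taken as tags plus 1 over background plus 1 and a Poisson p-value. A solution within 0.001 of the -log10 p-value was found for 100% of peaks in every list. The recovered backgrounds were multiples of 0.02 or 1 value per library, which was taken as that library's genome background and as a measure of relative depth. This reading of the caller's model was inferred from the values. It assumes the same effective genome size in every list. The smallest tag number called at the genome background was 12, 8 and 10 in naive libraries 1, 2 and 3 and 10, 11 and 10 in burned libraries 1, 2 and 3. Every peak had a q-value below 0.05. The lowest -log10 p-value in a list was 4.45, 3.97 and 4.53 in naive libraries 1, 2 and 3 and 5.24, 5.20 and 4.30 in burned libraries 1, 2 and 3.

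Peaks of all lists were merged where they shared at least 1 bp, and a region counted as called in a library with a peak in it. Peaks were divided into those on chromosomes 1 to 21 and X and those on unplaced scaffolds. Group means were compared with the exact two-sided permutation test over the 10 splits of 6 libraries, whose smallest p is 0.1. Counts of regions called in all libraries of one group and none of the other were set against the other splits. Shares of single libraries have 95% Wilson intervals, which cover counting error only. Intervals of height ratios and of areas under the ROC curve come from resampling regions and do not cover the spread between corneas. The inversion was tested on 2414 simulated peaks, with the tag number recovered for 100%. The assignment of regions to classes was tested on 2500 simulated regions, all of which came out in their true class. The simulated peaks were made with the same formula, and the simulated regions lay far apart. These tests therefore check the code and not the reading of the caller's model. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Coordinates are given from 1.

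The tests, the merging and the rule for named regions were fixed before the data were examined. The rule took the 10 regions per direction called in 3 of 3 libraries of one group and 0 of 3 of the other with the highest mean fold, and the 5 regions called in all 6 libraries with the highest mean fold. It also covered 22 genes chosen in advance and members of 17 gene lists. The comparison of chromosomes with unplaced scaffolds and the counts per chromosome were added after the lists were seen. Alternatives were a stricter q-value limit (-log10 of at least 5), chromosomes alone, equal list lengths, coverage of at least 50% of a region, leaving out each library, and the replicate number as a block. Alternatives added later were 1 p limit for all lists, peaks with a local background under 1.5 times the genome background, and the lists without the longest of each group.

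The gene table at hand belongs to another build, mOryCun1.1, so no gene annotation or genome sequence of OryCun2.0 was used. Peaks could therefore not be linked to genes or searched for sequence motifs. The planned share of peaks near transcription starts, the 17 gene lists, the 22 genes and the 33 motif patterns were not analysed here, and regions are described by position alone.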

Results

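Open chromatin was measured by ATAC-seq, in which a transposase inserts sequencing adaptors where DNA is accessible, in 6 corneas of female rabbits. The 3 burned corneas had been exposed to sodium hydroxide, which injures the corneal surface and stroma, and were collected on day 14. The 3 naive corneas were untreated, and according to the labels the eye opposite a burned one served as the naive control. Each library has its own list of peaks, positions where tags exceeded the local background, on the rabbit build OryCun2.0. Total read numbers were not given in the sources used here. The lists themselves gave the relative depth: the genome background, the tags expected at a position by chance, was 2.77, 1.79 and 1.8 tags in naive libraries 1, 2 and 3, and 1.83, 2.11 and 1.92 tags in burned libraries 1, 2 and 3. The group means did not differ beyond the spread between libraries (exact two-sided permutation test, p = 1, n = 3 per group). With 3 libraries against 3, this test cannot give a p below 0.1.

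The question in this design is how accessible chromatin of the burned cornea differed from that of the naive cornea. The peak lists of the burned libraries held fewer peaks than those of the naive libraries, and the difference lay mostly on the assembled chromosomes. Weaker signal over the same regions, or fewer distinct nuclear reads, stays possible in the burned libraries. The counts therefore do not show a loss of accessible regions in the burned cornea. The burned libraries held 2408, 2319 and 4406 peaks, against 8808, 21184 and 8416 in the naive libraries (3044 ± 1180 against 12803 ± 7261, mean ± SD, n = 3 each). On the log2 scale the difference of means, burned minus naive, was -2.0, which is a 4.00-fold lower number (exact two-sided permutation test, p = 0.1, the smallest possible). On chromosomes 1 to 21 and X, the burned libraries had 385, 314 and 1114 peaks and the naive libraries 4104, 15058 and 5023, a log2 difference of -3.72 or 13.2-fold (exact p = 0.1). On scaffolds that the assembly places on no chromosome, they had 2023, 2005 and 3292 against 4704, 6126 and 3393, a log2 difference of -0.96 or 1.94-fold (exact p = 0.1). The log2 ratio of chromosomal to unplaced peaks differed by -2.77 between the groups, with every burned library below every naive library (exact p = 0.1). With every list limited to its 2319 peaks of lowest p, the chromosomal difference was 3.68-fold and the unplaced difference 1.18 on the log2 scale, with more peaks in the burned libraries (exact p = 0.1 each). With a fixed total, these differences are the same result seen from both sides, and a loss on chromosomes cannot be told from a gain on unplaced scaffolds. With full lists, the exact p on unplaced scaffolds was 0.2 without any 1 of naive libraries 1, 2 and 3 or burned libraries 1 and 2.

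**Figure D1:**
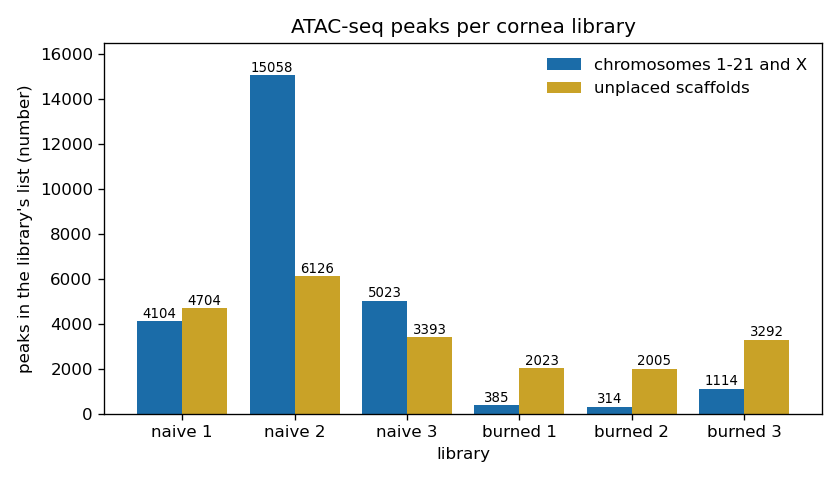
Number of ATAC-seq peaks in each library's list (vertical axis) for 3 naive and 3 burned corneas, with peaks on chromosomes 1 to 21 and X in blue and peaks on unplaced scaffolds in yellow. Burned libraries had 314 to 1114 chromosomal peaks and naive libraries 4104 to 15058.

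Chromosomal peaks made up 16.0%, 13.5% and 25.3% of the lists of burned libraries 1, 2 and 3 (95% Wilson intervals 14.6 to 17.5, 12.2 to 15.0 and 24.0 to 26.6). In naive libraries 1, 2 and 3 the shares were 46.6%, 71.1% and 59.7% (45.6 to 47.6, 70.5 to 71.7 and 58.6 to 60.7). The intervals cover counting error only. The group means were 18.3% ± 6.20 and 59.1% ± 12.3 (SD, n = 3 each, exact permutation test, p = 0.1). Peaks covered 910, 865 and 1528 kb of sequence in the burned libraries and 3051, 7618 and 2850 kb in the naive ones (exact p = 0.1 on the log2 scale, n = 3 per group).

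Peaks of the 6 lists that shared at least 1 bp were merged into 26220 regions, 16640 of them on chromosomes and 9580 on unplaced scaffolds. A peak was present in all 3 naive libraries at 2643 chromosomal regions, and 2154 of these (81.5%) had no peak in any burned library. Burned libraries 1, 2 and 3 had a peak at 161 (6.09%, Wilson interval 5.24 to 7.07), 151 (5.71%, 4.89 to 6.66) and 484 (18.3%, 16.9 to 19.8) of the 2643. On unplaced scaffolds, 1875 regions had a peak in all 3 naive libraries, and 573 of these (30.6%) had none in any burned library. There, the burned libraries had a peak at 56.7%, 56.9% and 65.1% of the 1875 regions. Burned library 3 lay above the other burned libraries on both kinds of sequence.

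**Figure D2:**
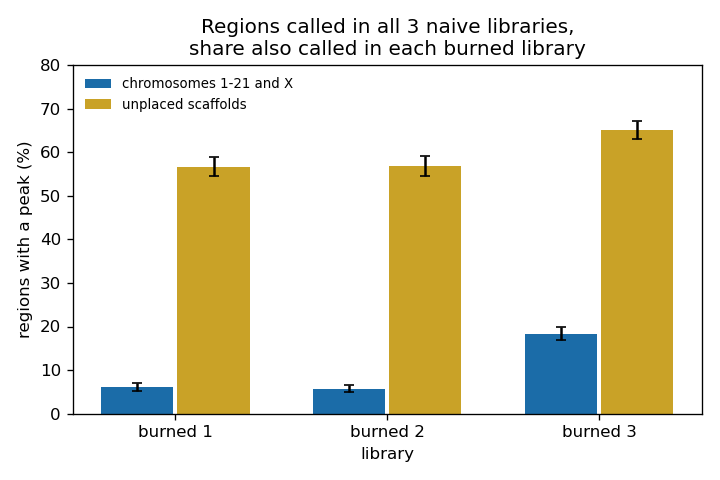
Share of the regions with a peak in all 3 naive libraries that also had a peak in each burned library (vertical axis, percent, with 95% Wilson intervals as error bars), for chromosomes 1 to 21 and X in blue (2643 regions) and unplaced scaffolds in yellow (1875 regions). The chromosomal shares were 6.09%, 5.71% and 18.3%, and the unplaced shares 56.7% to 65.1%.

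In all, 2727 regions had a peak in 3 of 3 naive and 0 of 3 burned libraries, with a median width of 522 bp. The naive-only regions with the highest fold enrichment over local background, a value of the authors for each peak, included chromosome 12 at 57126847 to 57127394 (10.5 ± 2.42, mean ± SD over 3 naive libraries). Chromosome 3 held the next 2 in rank, at 106705091 to 106705624 (10.4 ± 3.01) and 100870971 to 100871690 (10.2 ± 2.01). Chromosome 7 at 19578386 to 19579081 (10.1 ± 3.40) and chromosome 8 at 24803431 to 24803998 (9.98 ± 1.10) followed. The remaining 5 of the 10 named regions had mean folds of 9.50 to 9.70. These lay on chromosome 15 (31468964 to 31469426), chromosome 14 (126701503 to 126702069), chromosome 4 (67196073 to 67196863) and the scaffolds GL018888 (423241 to 423719) and GL018713 (480444 to 480946). At chromosome 12, 57126847 to 57127394, the summit held 41, 53 and 34 tags in naive libraries 1, 2 and 3. No gene annotation of this build was used, so the nearest genes of these regions are not reported. A region without a peak in a list is not shown to be closed, since the lists hold only positions above a limit. The count was 544 when every list was limited to its 2319 peaks of lowest p, the length of the shortest list, and 151 of the 544 overlapped a peak of a full burned list. It was 4943 without naive library 1. It was 473 with only peaks whose local background was under 1.5 times the genome background. All 10 named regions then lost a peak in at least 1 naive library and left the class. At chromosomal naive-only regions the median local background was 1.32, 1.89 and 1.48 times the genome background in naive libraries 1, 2 and 3. It rose with the median summit height, which was 7.59, 17.9 and 11.7 times the genome background. High peaks can thus leave this setting through their own signal, so it is no test of these regions.

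Regions with a peak in 3 of 3 burned and 0 of 3 naive libraries numbered 14, of which 11 lay on unplaced scaffolds. The 3 on chromosomes were at chromosome 16, 4296889 to 4297164 (fold 5.91 ± 0.802), chromosome 12, 152836979 to 152837354 (5.14 ± 0.140), and chromosome 14, 12644558 to 12644854 (4.92 ± 0.521; SD over 3 burned libraries). The highest folds among the 14 were on the scaffolds GL018801 at 231478 to 231740 (6.67 ± 0.445) and GL019784 at 1866 to 2215 (6.01 ± 0.881). Others of the 10 named regions lay on the scaffolds GL018812 (471314 to 471669, fold 5.49), GL018774 (36634 to 36958, fold 5.21), GL018701 (6943740 to 6944134, fold 4.8), GL019750 (17797 to 18368, fold 4.58) and AAGW02083773 (2750 to 3061, fold 4.40). Summits of these 10 regions held 12 to 29 tags. Of 1264 regions with a peak in all 3 burned libraries, 1250 (98.9%) had a peak in at least 1 naive library and 1051 (83.1%) in all 3. The naive lists are longer, which makes such overlap easier to reach. Of the 1051 regions, 912 lay on unplaced scaffolds, where sequence in more copies than the assembly shows could give a peak in any library. These shares are therefore not a measure of shared accessibility. At the stricter q limit 6 of the 10 named regions left the class, those on chromosomes 12 and 14 among them, and 4 left it at equal list length. The count was 206 with every list limited to its 2319 peaks of lowest p, of which 197 overlapped a peak of a full naive list. It also depended on single libraries and was 47 without naive library 1, 74 without burned library 1, 61 without burned library 2 and 26 without burned library 3.

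The 1051 regions with a peak in all 6 libraries lay mostly on unplaced scaffolds (912 regions, 86.8%), against 21% of the naive-only regions. At the 912 unplaced regions the local background was a median of 4.33 times the genome background, against 1.83 times at unplaced naive-only regions. The highest mean fold was on the scaffold AAGW02083802 at 1 to 282 (25.2 ± 1.38, SD, n = 6 libraries), at the start of that scaffold. Chromosome 12 at 96965504 to 96965897 had a fold of 21.9 ± 2.54, the only chromosomal region among the 5 named. With low local background only, this region kept a peak in 1 library, and 1 of the 5 named regions, that on GL019013, kept a peak in all 6. High peaks can leave this setting through their own signal. The others were on the scaffolds GL019013 at 255466 to 255788 (19.6 ± 1.07), GL018953 at 24307 to 24952 (19.1 ± 0.826) and AAGW02083596 at 5714 to 6165 (18.5 ± 1.55). At the chromosome 12 region, the summit held 119, 120 and 133 tags in naive libraries 1, 2 and 3 and 99, 71 and 110 tags in burned libraries 1, 2 and 3.

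**Figure D3:**
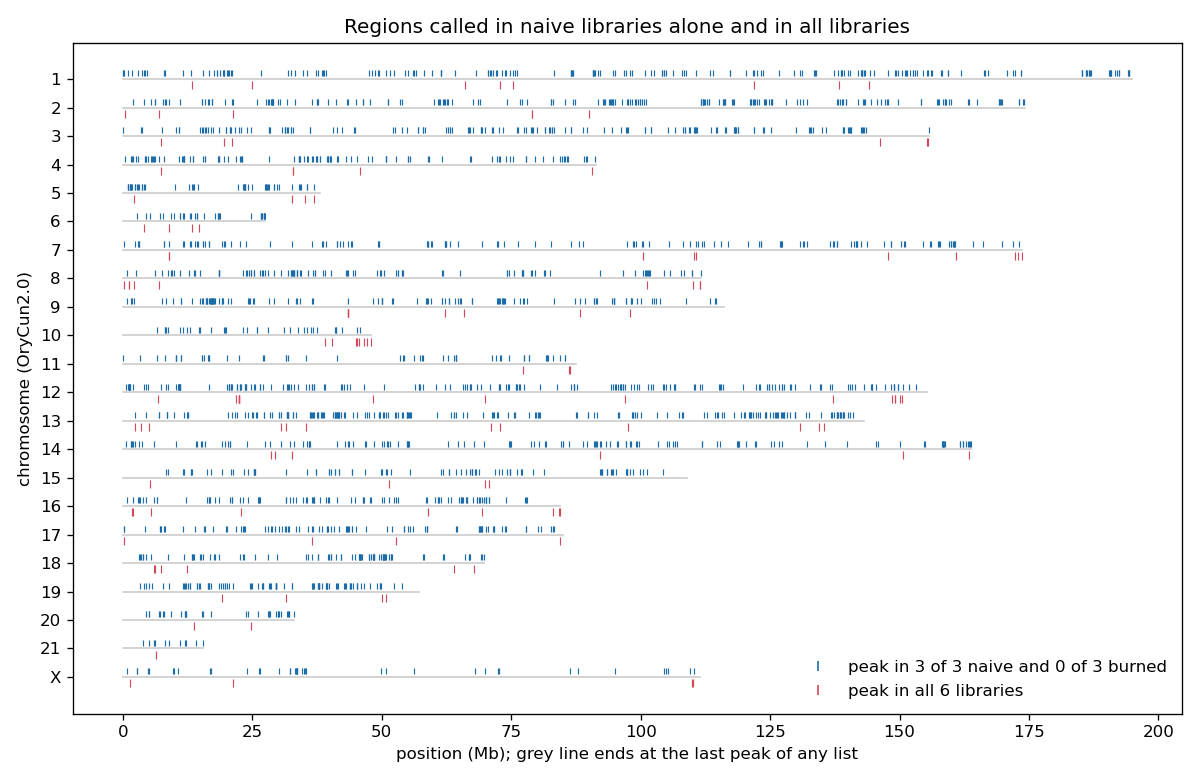
Positions of chromosomal regions along chromosomes 1 to 21 and X of OryCun2.0 (horizontal axis, Mb), with the 2154 regions called in 3 of 3 naive and 0 of 3 burned libraries in blue above each line and the 139 regions called in all 6 libraries in red below it. Each line ends at the last peak of any list, and regions of both kinds lay on all 22 chromosomes.

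On each of the 22 chromosomes, every burned library had fewer peaks than every naive library. By chance alone, 10% of chromosomes would separate the groups in this way in either direction, and chromosomes of one library are not independent. Chromosome 1 had 366, 1387 and 452 naive and 24, 16 and 90 burned peaks. On chromosome 8, 200, 661 and 224 naive peaks stood against 29, 19 and 79 burned ones, and on chromosome 10, 79, 274 and 90 against 19, 14 and 31. Chromosome 19 had 164, 558 and 195 naive and 7, 5 and 38 burned peaks. As a share of a library's chromosomal peaks, chromosome 8 made up 6.89% ± 0.761 in burned and 4.57% ± 0.261 in naive libraries, and chromosome 10 made up 4.06% ± 1.13 and 1.85% ± 0.0702 (SD, n = 3 each, exact p = 0.1 for both). Chromosomes 16 and 18 also had a higher share in all burned libraries, and chromosomes 1, 3, 4, 17 and 19 a lower one, at the same exact p. After Benjamini-Hochberg adjustment over the 22 chromosomes, the smallest p was 0.244. Since the exact p cannot go below 0.1, no shift between chromosomes could have passed a limit of 0.05.

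Lists of the same group overlapped more than lists of different groups. The Jaccard index, the share of regions of either library that both called, averaged 0.325 between naive libraries (0.247 to 0.422), 0.380 between burned libraries (0.339 to 0.451) and 0.160 between groups (0.0687 to 0.266). The mean within groups exceeded that between groups by 0.193 (exact p = 0.1 over the 10 splits of 6 libraries into 3 and 3). On chromosomes alone the averages were 0.311, 0.25 and 0.0563, and on unplaced scaffolds 0.360, 0.420 and 0.290, in the same order. Of the peaks of burned libraries 1, 2 and 3, 87.3%, 87.5% and 72.0% overlapped a peak of a naive library, whereas 37.9%, 12.2% and 30.3% of the peaks of naive libraries 1, 2 and 3 overlapped a burned one. These shares, like the Jaccard index, move with the lengths of the lists.

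**Figure D4:**
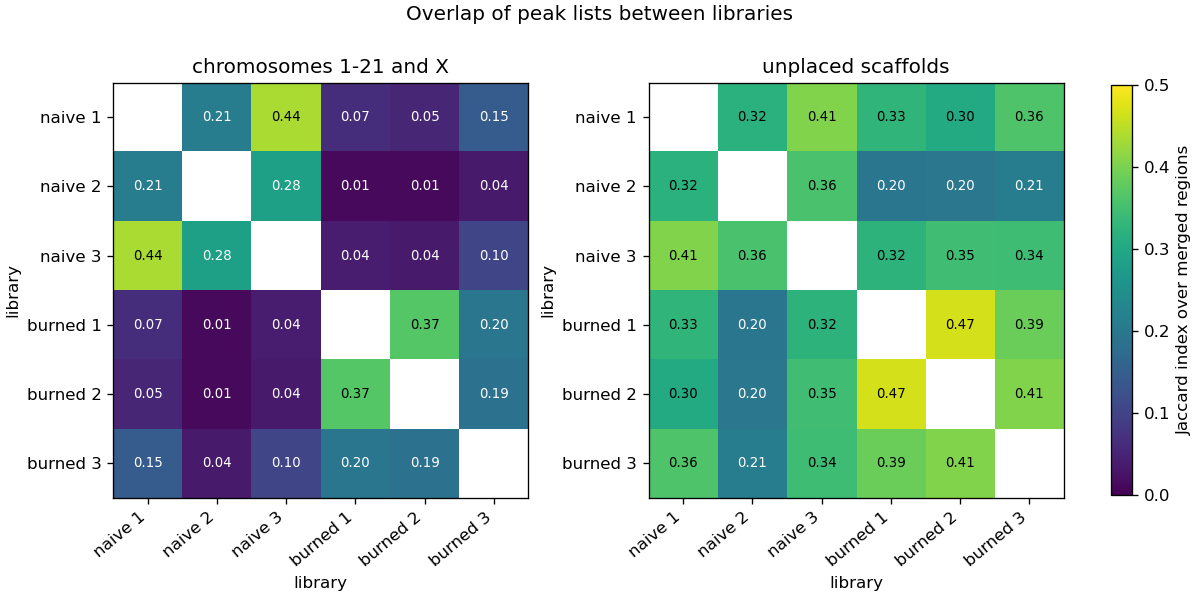
Jaccard index over merged regions for each pair of the 6 libraries, on chromosomes 1 to 21 and X (left) and on unplaced scaffolds (right), with the value printed in each square. Chromosomal values between groups averaged 0.0563, against 0.311 among naive and 0.25 among burned libraries.

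Median peak widths were 287, 316 and 290 bp in naive libraries 1, 2 and 3 and 293, 288 and 274 bp in burned libraries 1, 2 and 3, and the means differed by -12.7 bp, within the spread between libraries (exact p = 0.5, n = 3 per group). The width difference depended on which peaks were compared: it was -144 bp with lists of equal length, -47.3 bp on chromosomes alone and -22.7 bp with low local background (exact p = 0.1 each), and 2 bp, in the other direction, without the longest list of each group (exact p = 0.667). The authors' fold enrichment had a median of 4.18, 5.09 and 5.01 within the naive lists and 4.34, 4.22 and 4.39 within the burned lists. These medians describe each list alone.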

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

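The settings with 1 p limit, with low local background, and without the longest list of each group were chosen after the data were seen, as were the separate peak numbers on chromosomes and on unplaced scaffolds and the chromosomal share. The lower peak number of the burned libraries kept its direction in 12 of 12 alternatives (log2 difference -3.72 to -1.57), as did that on chromosomes (-4.28 to -1.88) and the chromosomal share (-47.1 to -34.9 percentage points). On unplaced scaffolds 11 of 12 did, and at equal list length (2319 peaks) the difference was 1.18, in the other direction. With a fixed total, a loss on chromosomes cannot be told from a gain elsewhere. Leaving out libraries, or the replicate block, could not reverse these counts or the share, since every burned library lay below every naive one. Only the settings that filter peaks tested their direction. The excess of overlap within groups kept its direction in 13 of 13 (0.108 to 0.25). The width difference kept its direction in 12 of 13 (-144 to 2 bp). It was -144 bp at equal list length, -47.3 bp on chromosomes alone and -22.7 bp with low local background (exact p = 0.1 each), and 2 bp without the longest list of each group. The cause was not tested.

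Naive-only regions numbered 544 at equal list length (151 of them overlapped a peak of a full burned list), 473 with low local background, and 2746 to 4943 with 1 library left out (4943 without naive library 1). Low local background means under 1.5 times the genome background. This setting can drop high peaks through their own signal, since local background rose with peak height. All 10 named naive-only regions then left the class. Of the 5 named regions with a peak in all 6 libraries, 1 stayed. Burn-only regions numbered 9 at the stricter q limit (6 of the 10 named left the class, and 4 at equal list length), 3 on chromosomes alone, 7 with low local background, 39 without the longest lists and 21 to 74 with 1 library left out (47 without naive library 1, and 74, 61 and 26 without burned libraries 1, 2 and 3). Leaving out libraries loosens the criterion by construction. At equal list length there were 206 burn-only regions, of which 197 overlapped a peak of a full naive list.

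With the library number as a replicate block, the log2 difference in peak number was -2.0 (exact sign-flip test, p = 0.25, the smallest possible), that on chromosomes -3.72 and that on unplaced scaffolds -0.96 (exact p = 0.25 each), the share -40.8 points (exact p = 0.25) and the width -12.7 bp (exact p = 0.5). Deviations of libraries with the same number correlated at -0.0587, 0.168 and 0.128 across regions. Naive library 1 correlated best with burned library 3 (0.157), whereas naive libraries 2 and 3 correlated best with the burned library of their own number. This mixed result cannot decide the pairing. The alternatives listed beforehand for promoter shares, gene lists and motifs were not run, for lack of an annotation and sequence of the build. The lists show no region below their limits, so weaker accessibility cannot be told from none.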

Other observations

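The tests of depth, of the p limit and of copy number were chosen after the result was seen. So was what the other splits of the libraries would have to show. The test of which naive regions the burned libraries kept was set before. The limit on the ratio of heights between naive libraries, used when that test was run, was not part of the plan. The windows named first were also chosen after their values were seen.

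Naive-only regions were counted in 1-Mb windows, with no test of clustering. The 1-Mb window of chromosome 12 from 10000001 to 11000000 held 10 of them, the highest number among 1126 windows with at least 1. The naive libraries had 14, 26 and 11 peaks in it and the burned libraries 0, 0 and 0. Chromosome 18 from 50000001 to 51000000 held 8 naive-only regions, with 9, 16 and 12 naive and 0, 0 and 1 burned peaks. Chromosome 12 from 20000001 to 21000000 held 7, with 17, 36 and 13 naive and 0, 0 and 1 burned peaks, and chromosome 8 from 32000001 to 33000000 held 7, with 15, 33 and 16 naive and 0, 0 and 2 burned peaks. Of the 10 scaffolds with the highest burned mean, GL019305 and GL018854 had a higher mean in the burned libraries, and all others a lower one. GL019305 had 14, 12 and 11 burned peaks against 15, 9 and 7 naive ones. GL018854 had 11, 9 and 19 against 11, 12 and 12, and neither difference was tested.

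The lower number of peaks in the burned libraries was set against 3 technical explanations. Lower depth in the tags kept by the caller is argued against by the genome background, whose burned mean was 0.921 times the naive mean. In addition, 2 naive libraries had a background below that of every burned library and still more peaks than each of them. The handling of duplicate and mitochondrial reads was not given, so fewer distinct nuclear reads in the burned libraries stay possible. A stricter p limit on summits in the shorter lists is argued against by a log2 difference of -1.99 with 1 p limit for all lists. That limit filtered the summits of peaks already called and kept 20876 of the 21184 peaks of naive library 2. Which stretches the caller would have found with 1 limit could not be tested, so a stricter limit in calling stays possible. A weaker signal over the same regions, as a smaller share of intact nuclei could give, stays open: among 2346 chromosomal regions called in all naive libraries and over 1.5 times as high in naive library 2 as in 1, mean naive height separated those that burned library 3 still called (area under the ROC curve 0.828, 95% interval 0.803 to 0.852), but in burned libraries 1 and 2 the areas were 0.660 (0.495 to 0.815) and 0.552 (0.394 to 0.701), from 15 and 17 called regions. Of the 2643 chromosomal regions called in all naive libraries, burned libraries 1, 2 and 3 called 161, 151 and 484. Only 15, 17 and 324 of these were over 1.5 times as high in naive library 2 as in 1. The areas thus leave out most regions that burned libraries 1 and 2 kept. A change in the cells that make up the burned cornea, or in their chromatin, is the biological explanation the design offers, and it was not tested.

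Regions called in all 6 libraries may hold sequence present in more copies than the assembly shows, which would give a peak at any level of open chromatin. On unplaced scaffolds, their height over the genome background was 1.10 times as high in naive library 2 as in naive library 1 (median of 912 regions, 95% interval 1.09 to 1.12). That of naive-only regions was 2.13 times as high (2.07 to 2.19). These intervals come from resampling regions of 2 libraries and leave out the spread between corneas. The local background at these 912 regions was 4.33 times the genome background, against 1.83 at naive-only regions. Such copies would give this, but higher peaks would also raise it. Median summit heights were 19.5, 21.8 and 22.8 times the genome background in naive libraries 1, 2 and 3, against 8.31, 17.3 and 11.7 at unplaced naive-only regions. How much of the contrast comes from height was not tested. For the 139 chromosomal regions the ratio of heights was 1.06 (1.01 to 1.12), but their local background was 1.33 times the genome background, against 1.56 at naive-only regions. That order held in naive libraries 2 (1.36 against 1.89) and 3 (1.37 against 1.48) and not in naive library 1 (1.35 against 1.32), so extra copies cannot be told apart from steady accessibility there, and no biological explanation was tested.

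With 10 splits of 6 libraries, no share under 0.05 can be reached. The real split gave 2727 naive-only regions and was 1 of 10 with as many, the highest other split giving 101. These lists differ in length, and the real split sets the 3 longest against the 3 shortest, so list length alone raises this count. With lists of equal length, chosen after the result was seen, the real split gave 544 and the highest other 70. For burn-only regions the real value was 14, and 5 of the 10 splits gave at least as many in both directions, the highest other giving 36. Here the unequal list lengths lower the real value. With lists of equal length the real split gave 206, and the highest other gave 8 in both directions. Of these 206 regions, 197 overlapped a peak of a full naive list.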
